A study of Mus musculus with 72 samples.

How the data were processed

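The data are read counts per probe from a TempO-Seq assay of 72 liver libraries, 9 in each of 8 groups of dose and duration, deposited as 1 table of 30146 probes. The values are whole-number counts as the authors deposited them, neither scaled nor logged. The library depths given below are the sums of these columns. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20 and aligned with Bowtie, whose version, like the genome build and the counting tool, is not given in the sources used here. Groups were taken from the labels for dose and duration. The labels give no batch, plate or pairing of animals, so none could be modelled, and replicates are numbered in the order in which the samples are listed.

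Probe names were split into a symbol and a number. Of 21400 symbols, 15091 have 1 probe and 6309 have more (up to 6), and 21069 matched the reference gene names. A probe was treated as a feature of its own. Libraries with under 100000 counts were left out, which removed replicate 5 of the 40 mg/mL group at 14 d (0.0108 M counts). The median of the libraries kept was 10079945. Features with low counts were removed by filterByExpr over the 8 groups, which left 17050 features of 11784 symbols (13096 fell below the filter) with 99.9% of all counts. No pair of libraries within a group was a duplicate (smallest chi-square per degree of freedom 7.15, 0 identical columns). Pairs from different groups were not checked. Spearman correlations within groups were 0.903 to 0.968 (median 0.949), and 0 libraries lay under the limit of 0.898, set 3 median absolute deviations below the median.

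Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM scaling, a quasi-likelihood fit with robust estimation and 1 mean per group over all 71 libraries (common biological coefficient of variation 0.402), and Benjamini-Hochberg adjustment at 0.05 within each comparison. The comparisons were each dose against the control of the same duration, a linear trend over doses (log2 change per 10 mg/mL), the difference of each dose effect between durations and the 28 d against the 14 d controls. Gene lists (24) and cell type marker lists (11), written from textbook knowledge, were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation. Tests of lists were adjusted over the lists of a comparison. Members were also counted after adjustment over the list alone. The lists share genes, so their results are not independent. Tf alone among the listed genes was absent from the file, and no adipocyte marker passed the filter. Library totals and the 19 measured always-named genes (114 tests on log2 CPM with a prior count of 2) were compared by exact permutation, whose smallest p with 9 against 9 animals is 4.11e-05. Overlaps between doses share their controls and were set beside simulated unchanged groups and split controls.

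Genes to name were set by 1 rule: 20 genes always named, chiefly enzymes and carriers that dispose of thyroid hormone, the 10 largest changes each way at 40 mg/mL among features that passed with a mean of at least 5 CPM, up to 4 members of each list with the smallest p in the 2 comparisons at 40 mg/mL, and up to 5 each way for the interaction and control comparisons. The probe with the highest mean count stood for a gene, and genes whose other probes differ in call are named. List members that did not pass are counted, and only some of them named. The result of 1 always-named gene is not reported here. Genes named for the other comparisons were picked from their calls. The rule, groups, lists, tests and most alternatives were fixed before the data were examined.

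Alternatives were DESeq2 1.42.0, limma with quality weights, edgeR without robust fitting, size factors of DESeq2 in place of TMM, scaling without the 20 most abundant features, no filter, a filter at 5 CPM, the groups of a comparison alone, 2 surrogate variables (sva 3.50.0), probes summed per gene and leaving out each library in turn. A further 5 were chosen after the data had been seen: the failed library kept, the 2 libraries with the highest scaling factors left out, the log2 scaling factor as a covariate, the exact tests of named genes and the library totals without the failed library. The tests were tried on simulated data shaped like 40 mg/mL vs control at 14 d, with 200 of 16412 features changed. edgeR recovered 28.4% of 1.5-fold, 53.7% of 2-fold and 90.9% of 4-fold changes, and 6 of 121 calls were false (4.96%). DESeq2 recovered 29.9%, 56.7% and 93.9% (12 of 132 calls false, 9.09%) and limma 22.4%, 47.8% and 84.8% (3 of 106, 2.83%). In edgeR 2 comparisons simulated without change also gave calls. A changed list reached a camera adjusted p of 1.43e-59 with the preset and 3.06e-25 with the estimated correlation. There 0 unchanged lists were called, and 2 of 100 permutation tests of unchanged data gave a p under 0.05. The simulated features varied independently, without the differences in composition of the real libraries, so the rates of false calls may be higher in the real data.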

Results

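The counts came from TempO-Seq, an assay that ligates and sequences pairs of detector oligos bound to chosen transcripts, run on scraped sections of formalin-fixed, paraffin-embedded liver from 72 female B6C3F1 mice. Tertiary butyl alcohol (TBA) was given in drinking water at 0, 10, 20 or 40 mg/mL for 14 or 28 d, with 9 animals in each of 8 groups and 1 library per animal. Each of the 30146 features is a probe written as a gene symbol and a probe number, such as Cyp2b10_30803, and the file gives no genome coordinates. Each gene is represented below by its probe with the highest mean count. The library of replicate 5 at 40 mg/mL for 14 d held 0.0108 M (mega) counts and was left out by a depth limit fixed before the data were examined, so that group has n = 8. The other 71 libraries held 7.77 to 12.7 M counts. The series title asks whether an anti-thyroid mode of action could lie behind thyroid tumours in dosed female mice. Each comparison with control therefore asks which liver transcripts differed, with weight on the enzymes, transporters and carriers that dispose of thyroid hormone. The comparisons between durations ask whether those differences changed from 14 to 28 d.

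Mean library totals at 0, 10, 20 and 40 mg/mL were 10.7 ± 1.19, 10.2 ± 0.835, 10.1 ± 1.49 and 10.1 ± 1.30 M counts at 14 d (SD, n = 9, and n = 8 at 40 mg/mL). The same doses gave 9.32 ± 0.932, 9.91 ± 0.855, 10.5 ± 1.15 and 9.58 ± 1.12 M counts at 28 d (SD, n = 9). The smallest p for a dose group's total was at 20 mg/mL for 28 d, 1.23 M counts above control (exact permutation p = 0.0266, adjusted p = 0.159). At 40 mg/mL for 14 d the difference was -1.71 M counts with the failed library (exact permutation p = 0.168) and -0.591 M counts without it (exact permutation p = 0.336). The composition of the libraries differed more than their size. The 20 most abundant features took 22.5% ± 1.02 of counts in 14 d controls (SD, n = 9) and 14.7% ± 3.65 at 40 mg/mL for 14 d (SD, n = 8). Scaling factors by the trimmed mean of M values (TMM) were 0.897 ± 0.0336 and 1.24 ± 0.247 in the same groups. Replicates 7, 1, 2 and 8 at 40 mg/mL for 14 d stood apart with factors of 1.58, 1.55, 1.39 and 1.30, as did control replicate 3 at 28 d with 1.37. Factors were also high in replicates 9 and 1 at 20 mg/mL for 28 d (1.48 and 1.30) and in replicates 7 and 6 at 40 mg/mL for 28 d (1.40 and 1.35). Replicate 9 at 20 mg/mL and replicate 2 at 10 mg/mL for 14 d both had 1.26. Several gene groups below move with these libraries.

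At 40 mg/mL for 14 d, 1111 of 17050 tested features passed (484 higher, 627 lower; 933 symbols), and male-biased genes of the liver were lower. Of the 11 measured male-biased liver genes, whose expression depends on the pulsed growth hormone pattern of males, 7 fell, 0 rose and 4 did not pass; adjusted over the list alone all 11 fell. Mup20, a major urinary protein that carries pheromones, was 2.95-fold lower (log2FC -1.56, SE 0.31), and the protease inhibitor Serpina1e was 2.11-fold lower (log2FC -1.08, SE 0.22, adjusted p = 0.000859; 5.24-fold lower by its other probe Serpina1e_62853, log2FC -2.39, SE 0.47). For each of these 8 of 8 animals were below all controls. Cyp7b1, which hydroxylates oxysterols on the way to bile acids, fell by 1.68 log2 units (SE 0.33, adjusted p = 0.00074), and Elovl3, a fatty acid elongase, was 3.41-fold lower (log2FC -1.77, SE 0.46, adjusted p = 0.0108). Outside the list, further major urinary proteins were lower in all 8 animals than in every control: Mup16 4.05-fold lower (log2FC -2.02, SE 0.28, adjusted p = 5.86e-06), Mup15 3.93-fold lower (-1.97, SE 0.28), Mup7 4.68-fold lower (-2.23, SE 0.38) and Mup19 4.81-fold lower (-2.27, SE 0.40). Slc22a28, an organic anion carrier gene and also outside the list, was 4.46-fold lower (log2FC -2.16, SE 0.44), and Gm10681 was 16.4-fold lower (log2FC -4.04, SE 0.78), each in 8 of 8 animals; without dosed replicate 6 Gm10681 had log2FC -4.97. The median of the male-biased list was -1.68 (n = 8 against 9; camera adjusted p = 4.9e-10 with the preset correlation and 0.0089 with an estimated correlation). The count of fallen members was 1 with the log2 scaling factor as a covariate and 3 without replicates 1 and 7, while Mup7, Mup15, Mup16, Mup19, Cyp7b1, Slc22a28 and Gm10681 passed in every alternative run; Mup20 and both Serpina1e probes were lost with the covariate (adjusted p = 0.118 for Mup20, 0.154 and 0.0503 for the probes), Serpina1e also with the failed library kept (0.0586), and Elovl3 with the covariate (0.169), in limma (0.0522) and without replicates 1 and 7.

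Genes that make fatty acids and triglycerides rose in the same livers. Of 19 measured members, 10 rose, 0 fell and 9 did not pass (13 rose adjusted over the list alone). Acaca, the enzyme of the first committed step, rose 2.76-fold (log2FC 1.46, SE 0.27, adjusted p = 0.000367, n = 8 against 9) from 72.5 ± 12.2 to 200 ± 138 CPM (SD), and was above all controls in 7 of 8 animals. Its mitochondrial counterpart Acacb rose 2.86-fold (log2FC 1.52, SE 0.33), the synthase Fasn 3.18-fold (log2FC 1.67, SE 0.39) and the elongase Elovl6 4.68-fold (log2FC 2.23, SE 0.44), in 6, 7 and 7 of 8 animals. Pnpla3, a lipase of lipid droplets, rose 7.05-fold (log2FC 2.82, SE 0.71, adjusted p = 0.00851), and 6 of 8 animals were above all controls. Acly and Me1, which supply the carbon and the reducing power for the pathway, rose 3.21-fold (log2FC 1.68, SE 0.39) and 3.19-fold (log2FC 1.67, SE 0.39). Across the list the median was 1.05 (camera adjusted p = 6.4e-05 with the preset correlation and 0.22 with an estimated correlation), and the count of risen members was 5 with the failed library kept. Acaca, Acacb, Fasn and Elovl6 passed in every alternative run, but without dosed replicate 3 Elovl6 had log2FC 1.43, and its second probe Elovl6_32029 (2.16) had 1.17 and was lost (adjusted p = 0.0954). Pnpla3 was lost with the log2 scaling factor as a covariate (adjusted p = 0.0646) and without replicates 1 and 7 (0.0531), and Acly and Me1 without dosed replicate 3 (log2FC 1.05 in both, adjusted p = 0.0538 and 0.0581) or with the failed library kept (0.0545 and 0.0549).

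UDP-glucuronosyltransferases conjugate thyroxine and other compounds for excretion. Of 19 measured members of their list, 6 fell at 40 mg/mL for 14 d, 0 rose and 13 did not pass (9 fell adjusted over the list alone). That list also held Ugdh, Ugp2, Ugt3a1 and Ugt3a2, which are not glucuronosyltransferases. Its counts and median are therefore not of thyroxine-conjugating enzymes alone. Ugt2b1 was 2.51-fold lower (log2FC -1.33, SE 0.26, adjusted p = 0.000764), at 38.7 ± 19.4 against 97.2 ± 17.7 CPM (SD, n = 8 and 9), and was below all controls in 7 of 8 animals. Ugt1a1, the transferase that conjugates bilirubin and thyroxine, was 1.90-fold lower (log2FC -0.93, SE 0.25, adjusted p = 0.0151), at 1473 ± 839 against 2805 ± 299 CPM, in 6 of 8 animals. Ugt2a3 was 1.87-fold lower (log2FC -0.91, SE 0.19) and Ugt3a2 1.68-fold lower (log2FC -0.75, SE 0.16), each in 7 of 8. The other members named in advance did not pass: Ugt1a6a had log2FC -0.76 (adjusted p = 0.31), Ugt1a9 -0.29 (0.867), Ugt2b34 -0.46 (0.168) and Ugt2b35 0.21 (0.514). By exact permutation on log2 CPM, Ugt1a1 (difference -1.21, adjusted p = 0.00261) and Ugt2b1 (-1.44, 0.00117) were lower. Ugt1a6a, Ugt1a9, Ugt2b34 and Ugt2b35 did not pass there either, and these tests use the same scaling factors. The median of the whole list was -0.46 (camera adjusted p = 5.7e-06 with the preset correlation and 0.15 with an estimated correlation). With the log2 scaling factor as a covariate 0 members fell, and Ugt1a1 had log2FC -0.09 (adjusted p = 0.833), Ugt2b1 -0.50 (0.171), Ugt2a3 -0.21 (0.362), Ugt3a2 -0.25 (0.272), Ugt1a6a 0.01, Ugt1a9 1.63 (0.0222) and Ugt2b34 0.24. Without replicates 1 and 7, 2 members fell, and Ugt1a1 had log2FC -0.62 (adjusted p = 0.214) and Ugt3a2 -0.61 (0.0539). Ugt1a1 was also lost with the 2 groups fitted alone (adjusted p = 0.0697), with the failed library kept (0.0928) and without replicate 1 or 7 singly (highest 0.0586); Ugt1a9 was 0.34 with surrogate variables and 0.07 without both replicates, and Ugt2b35 -0.15 with probes summed.

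Of 20 measured genes of thyroid hormone transport and deiodination, 5 fell, 0 rose and 15 did not pass (1 rose and 9 fell adjusted over the list alone). Slco1a1, an uptake carrier of organic anions, was 4.27-fold lower (log2FC -2.10, SE 0.59, adjusted p = 0.0196, 6 of 8 animals below all controls). The plasma carriers Ttr and Alb were 1.56-fold lower (log2FC -0.64, SE 0.20, adjusted p = 0.0352) and 1.65-fold lower (log2FC -0.72, SE 0.22, adjusted p = 0.0368), each in 6 of 8. This list shares 2 measured genes, Ttr among them, with the hepatocyte marker list described below. Dio1, the deiodinase that activates thyroxine, did not pass at its most abundant probe (log2FC -0.71, SE 0.28, adjusted p = 0.119, 4 of 8 animals), nor at Dio1_31468 (-0.49, adjusted p = 0.198) or Dio1_73779 (-0.44, adjusted p = 0.283), while the probe Dio1_31911 fell (log2FC -0.82, adjusted p = 0.00678). Exact permutation tests on log2 CPM gave Dio1 a difference of -0.85 (adjusted p = 0.03) and Ttr one of -0.79 (adjusted p = 0.0375). The median over these transporters was -0.46 (camera adjusted p = 0.00016 with the preset correlation and 0.19 with an estimated correlation). The count of fallen members was 0 with the 2 groups fitted alone, with the covariate or without replicates 1 and 7, and 2 with the failed library kept. Ttr was lost without control 1, 4 or 8 or dosed 1, 2, 7, 8 or 9 (highest adjusted p = 0.12), Slco1a1 without dosed 1, 7 or 8 (0.0568) and Alb without control 1, 2, 4, 8 or 9 or dosed 1, 2, 7, 8 or 9 (0.118). With the covariate Ttr had log2FC -0.07 (adjusted p = 0.873) and Dio1 0.04.

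Thyroid hormone responsive genes were counted beside all tested features, of which 1111 of 17050 passed. Of 17 measured members 4 rose, 0 fell and 13 did not pass (5 rose and 1 fell adjusted over the list alone). The 4 that rose, Acaca, Me1, Fasn and Thrsp, all serve fatty acid synthesis, and Thrsp, a regulator of that pathway, rose 3.58-fold (log2FC 1.84, SE 0.54, adjusted p = 0.0271, n = 8 against 9) with 5 of 8 animals above all controls and 2 below. The median of the list was 0.09 (camera adjusted p = 0.33). Members risen numbered 2 with the failed library kept, and Thrsp passed in neither limma (log2FC 0.95, adjusted p = 0.433) nor the exact permutation test (1.14, adjusted p = 0.246) and was lost without control replicate 9 or dosed replicate 1, 8 or 9 (highest adjusted p = 0.0943). Sulfotransferases, which sulfate hormones and drugs, did not move as a list, which also held Papss1 and Papss2, not themselves sulfotransferases. In it 1 of 15 measured members rose and 0 fell, with the same counts adjusted over the list alone (median 0.15, camera adjusted p = 0.6). The member that rose was Sult1e1, the oestrogen sulfotransferase, at 30.1-fold (log2FC 4.91, SE 1.32, adjusted p = 0.0142). Only 2 of 8 animals were above all controls for Sult1e1, and without replicate 9 the value was 1.09 (adjusted p = 0.719), with 0.98 in DESeq2 and 1.88 in limma (adjusted p = 0.486). Sult1a1 had log2FC 0.28 (adjusted p = 0.399), Sult1d1 0.91 (0.104; -0.20 without replicate 9) and Sult2a1 1.23 (0.314).

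Cyp2b10, the cytochrome P450 used as a marker of the constitutive androstane receptor (CAR), rose 17.1-fold at 40 mg/mL for 14 d (log2FC 4.09, SE 0.81, adjusted p = 0.000796, n = 8 against 9), but only 4 of 8 animals were above all controls and 1 was below. Mean expression was 1080 ± 2206 CPM (SD) against 63.2 ± 25 in controls, and the second probe Cyp2b10_71476 had log2FC 3.94 (SE 0.83, adjusted p = 0.00171). Among 23 measured targets of CAR and the pregnane X receptor (PXR), 2 rose, 2 fell and 19 did not pass (3 rose and 2 fell adjusted over the list alone). Besides Cyp2b10 the stress gene Gadd45b rose (log2FC 1.88, SE 0.52, adjusted p = 0.0186), and Cyp2c54 (-1.16, SE 0.37, adjusted p = 0.0414) and Cyp3a41a (-1.04, SE 0.33, adjusted p = 0.0457) fell. Drug-metabolising targets named in advance did not pass: Cyp2c29 had log2FC 1.15 (adjusted p = 0.0722), Cyp3a11 -0.38 (0.557) and the reductase Por 0.83 (0.141). The CAR and PXR median was -0.12, the mean 0.22 and the camera direction down (adjusted p = 0.21). Replicate 9 carried much of the rise: without it Cyp2b10 had log2FC 2.32, the second probe had adjusted p = 0.0644 and Gadd45b log2FC 0.36 (adjusted p = 0.752). Cyp2b10 was lost in limma (log2FC 1.84, adjusted p = 0.122) and in the exact permutation test (1.87, adjusted p = 0.148). The count of risen members was 1 with the groups fitted alone or the failed library kept, 0 in limma and 5 with the covariate, where Cyp3a11 was 0.62 and Cyp2c54 0.06; Cyp2c54 was lost without control 1, 2, 3, 4, 7 or 8 or dosed 1, 2, 3, 4, 6 or 7 (highest adjusted p = 0.114) and Cyp3a41a without control 1, 2, 5, 6, 8 or 9 or dosed 1, 2, 3, 6, 7, 8 or 9 (0.123).

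Genes from both ends of the liver lobule were among those that fell. Of 11 measured pericentral genes 6 fell and 5 did not pass, and of 13 periportal genes 5 fell and 8 did not pass, with 0 rising in either and the same counts adjusted over each list alone. Cyp2e1 and Cyp1a2, cytochrome P450 enzymes of pericentral hepatocytes, were 2.43-fold lower (log2FC -1.28, SE 0.26, adjusted p = 0.000736) and 2.71-fold lower (log2FC -1.44, SE 0.31, adjusted p = 0.00209), each in 8 of 8 animals. The periportal enzyme Cyp2f2 was 2.65-fold lower (log2FC -1.41, SE 0.24, adjusted p = 0.00012) in 8 of 8, the adhesion protein gene Cdh1 2.23-fold lower (log2FC -1.16, SE 0.21) in 6 of 8, and Pigr, the receptor that moves immunoglobulin into bile, 2.47-fold lower (log2FC -1.31, SE 0.32) in 7 of 8. Hepatocyte markers followed: 4 of 7 fell and 0 rose (5 fell adjusted over the list alone), among them Serpina1a, 1.71-fold lower (log2FC -0.78, SE 0.17), and Apoa1, the main protein of high-density lipoprotein, 2.23-fold lower (log2FC -1.16, SE 0.32). Medians were -0.80, -0.52 and -0.64 for the pericentral, periportal and hepatocyte lists (n = 8 against 9; camera adjusted p = 2.2e-05, 1.5e-07 and 6.4e-05 with the preset correlation, and adjusted p = 0.081, 0.082 and 0.079 with an estimated correlation). Fallen members numbered 0, 2 and 1 with the covariate and 3, 2 and 1 without replicates 1 and 7; the failed library gave 3 periportal and 0 hepatocyte calls, and the 2 groups alone 1 hepatocyte call. Cyp2f2 and Cdh1 passed in every alternative run, Cyp2e1 and Cyp1a2 were lost with the covariate only (adjusted p = 0.18 and 0.392), Pigr there (0.58) and without replicates 1 and 7 (0.102), Serpina1a with the failed library kept (0.0628), and Apoa1 without replicate 1 or 7 singly (highest 0.0578) and in all 3 of these alternatives.

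Some bile acid and alcohol-metabolising genes fell too. Of 19 measured genes of bile acid synthesis and transport 6 fell, 1 rose and 12 did not pass (2 rose and 8 fell adjusted over the list alone). Cyp8b1, which sets the share of cholic acid, was 1.91-fold lower (log2FC -0.94, SE 0.27, adjusted p = 0.0209), the export pump Abcb11 1.56-fold lower (log2FC -0.65, SE 0.17) and the growth factor receptor Fgfr4 1.41-fold lower (log2FC -0.50, SE 0.10, adjusted p = 0.00144), each in 7 of 8 animals. The member that rose, Abcc4, pumps bile acids back into blood (5.93-fold, log2FC 2.57, SE 0.70, adjusted p = 0.0151). The bile acid median was -0.39 (camera adjusted p = 0.00067 with the preset correlation and 0.082 with an estimated correlation). Of 10 measured alcohol and aldehyde enzymes 5 fell, 1 rose and 4 did not pass (2 rose and 6 fell adjusted over the list alone). Cyp2e1, Adh4 (log2FC -0.70, SE 0.22, adjusted p = 0.0366), Adh5 (-0.35, SE 0.11, adjusted p = 0.0354), Aldh2 (-0.40, SE 0.13, adjusted p = 0.0444) and Aldh1b1 (-0.65, SE 0.20, adjusted p = 0.0331) fell, while Aldh3a2, which oxidises fatty aldehydes, rose 1.62-fold (log2FC 0.69, SE 0.18, adjusted p = 0.0119). That list's median was -0.35 (camera adjusted p = 0.021 with the preset correlation and 0.38 with an estimated correlation). Fallen bile acid genes numbered 2 with the covariate and 2 without replicates 1 and 7; fallen alcohol genes numbered 0 and 1 there, 1 with no expression filter, 3 in limma or with the groups alone and 1 with the failed library kept. Single libraries ended calls too: Cyp8b1 without replicate 1, 2 or 8 (highest adjusted p = 0.0618), Abcc4 without 9 (log2FC 1.86, adjusted p = 0.109), Adh5 without control 1 or 7 or dosed 1, 2 or 7 (0.0899), Aldh1b1 without control 3, 7 or 8 or dosed 1, 2, 7 or 9 (0.084), Adh4 without control 1, 2, 4 or 7 or dosed 1, 7, 8 or 9 (0.104) and Aldh2 without control 1, 2, 3, 4, 7, 8 or 9 or dosed 1, 2, 7, 8 or 9 (0.131). Fgfr4 passed in every alternative run, while the other bile acid and alcohol genes given here were lost with the covariate, where Aldh2 turned direction (0.0017), apart from Cyp2e1 also without replicates 1 and 7, and Abcb11 (0.179) and Aldh3a2 (0.5) with the failed library kept.

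Transcripts of dividing cells rose in some of the animals. Of 30 measured cell cycle genes 11 rose, 0 fell and 19 did not pass (20 rose adjusted over the list alone), and 29 had positive values. Birc5, an inhibitor of apoptosis made in mitosis, rose 11.7-fold (log2FC 3.55, SE 0.64, adjusted p = 0.000207, n = 8 against 9), the kinase Cdk1 7.59-fold (log2FC 2.92, SE 0.62) and Rrm2, which makes deoxynucleotides, 3.75-fold (log2FC 1.91, SE 0.41); 4, 5 and 5 of 8 animals were above all controls. The mean of the list was above all controls in 4 of 8 animals and below all of them in 2. The proliferation marker Mki67 rose 10.4-fold (log2FC 3.38, SE 0.96, adjusted p = 0.0204) in 4 of 8, with 1 of 8 below all controls on log2 CPM, but its second probe Mki67_30147 did not pass (log2FC 2.29, adjusted p = 0.147), nor did Mki67 by exact permutation (log2 CPM difference 1.47, adjusted p = 0.363). The median of the list was 1.52 (camera adjusted p = 0.00067 with the preset correlation and 0.38 with an estimated correlation). Without replicates 1 and 7 the count was 0, Birc5 had log2FC 1.94 (adjusted p = 0.0678) and Mki67 1.47 (0.595). The count was 2 with the groups alone, 2 in limma, 6 with surrogate variables, 1 with the covariate and 7 with the failed library kept. Without replicate 7 alone Birc5 had log2FC 2.44 and still passed, while Mki67 (2.53, adjusted p = 0.135) and Cdk1 (1.49, 0.114) were lost, and Mki67 was lost without replicate 1 as well. Cdk1 and Rrm2 had log2FC 1.15 and 1.17 without both replicates (adjusted p = 0.385 and 0.132), and Mki67 had log2FC 0.99 in limma and 1.75 with the covariate.

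Stress and xenobiotic programmes other than CAR gave a mixed picture. Of 18 measured targets of NRF2, the oxidant-response factor, 5 rose and 0 fell (7 rose adjusted over the list alone): the ferritin chains Ftl1 (1.56-fold, log2FC 0.64, SE 0.14, adjusted p = 0.0016, 8 of 8 animals above all controls) and Fth1 (1.40-fold, log2FC 0.49, SE 0.12), with Me1, G6pdx and Abcc4. Ferritin stores iron, and the others make reducing power or export conjugates. The NRF2 median was 0.41 (camera adjusted p = 0.0051 with the preset correlation and 0.21 with an estimated correlation). Peroxisome genes moved little: 2 of 29 PPARA targets rose, the acyl transferase Crat (2.67-fold, log2FC 1.42, SE 0.34, 8 of 8 animals) and the thioesterase Acot3 (3.71-fold, log2FC 1.89, SE 0.51), and 0 fell (same counts adjusted over the list alone; median 0.13, camera adjusted p = 0.21), while Cyp4a14 had log2FC 0.82 (adjusted p = 0.30). Of 5 aryl hydrocarbon receptor targets Cyp1a2 fell and 0 rose (2 rose and 1 fell adjusted over the list alone; median 0.68, camera adjusted p = 0.92), and Cyp1a1 was below the expression filter. Glutathione transferases divided, 2 of 21 rising (Gstm1, log2FC 0.77, SE 0.21, and Gstm4, 0.81, SE 0.21) and 2 falling (Gstk1, -0.84, SE 0.22, and Mgst1, -0.67, SE 0.18). In cholesterol synthesis 2 of 25 rose and 1 fell, and of 15 p53 targets 1 rose, Ccng1 (log2FC 0.55, SE 0.15, adjusted p = 0.0139). The NRF2 count was 3 with the groups alone or in limma, 8 with surrogate variables and 2 with the failed library kept. G6pdx and Me1 were lost without replicate 3 (0.132 and 0.0581), Abcc4 without 9 (0.109), and Mgst1 and Ccng1 without 1 or 7 (highest 0.0569 and 0.0688). Gstm1 and Gstm4 were lost without 8 (0.2 and 0.068), and the lowest log2FC of Gstm1 without 1 library was 0.433. Ftl1, Fth1 and Acot3 were lost with the failed library kept (0.549, 0.748 and 0.059), and Crat and Gstk1 with the covariate (0.368 and 0.983) and without replicates 1 and 7 (0.105 and 0.174).

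Several plasma proteins of inflammation fell, while most other lists held few calls. Of 23 measured acute phase and inflammation genes 4 fell, 0 rose and 19 did not pass (8 fell adjusted over the list alone). The clotting chain Fgg was 2.26-fold lower (log2FC -1.18, SE 0.27, adjusted p = 0.00378, 6 of 8 animals), the haem carrier Hpx 2.11-fold lower (log2FC -1.08, SE 0.26, adjusted p = 0.00477, 7 of 8) and the pentraxin Apcs 2.01-fold lower (log2FC -1.01, SE 0.27, 7 of 8). The acute phase median was -0.56 (camera adjusted p = 7.6e-08 with the preset correlation and 0.15 with an estimated correlation). Of 13 interferon response genes 1 fell, the viral tether Bst2 (log2FC -0.59, SE 0.14, adjusted p = 0.00467). Among 18 genes of the unfolded protein response 2 fell, the chaperones Pdia4 (log2FC -0.81, SE 0.25) and Hsp90b1 (-0.84, SE 0.26). Genes of the circadian clock (18) and of fasting (15) had 0 calls. Among markers of other cells, 0 of 9 Kupffer, 4 cholangiocyte, 6 T and NK, 6 B and 4 neutrophil markers passed, 1 of 9 sinusoidal endothelial and 2 of 11 stellate markers fell, and 1 of 3 erythroid markers, Hba-a2, rose (log2FC 1.56, SE 0.48, adjusted p = 0.0348), although it was lost without control 2, 3, 4, 8 or 9 or dosed 1, 2 or 7 (highest 0.165). Acute phase calls numbered 10 in DESeq2, 0 with the covariate and 0 without replicates 1 and 7; Bst2 was lost with the covariate, Pdia4 without control 1, 2 or 6 or dosed 1, 2, 7 or 8 (highest 0.121) and Hsp90b1 without control 1, 2, 3, 4 or 6 or dosed 1, 2, 6, 7 or 8 (0.12).

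Further genes with large changes at 40 mg/mL for 14 d lay outside these lists or completed them. Serpina9, a protease inhibitor best known from B cells, was 19.5-fold lower (log2FC -4.28, SE 0.82, adjusted p = 0.00051) and the dynein chain gene Dnaic1 4.59-fold lower (log2FC -2.20, SE 0.52, adjusted p = 0.00475), in 8 and 7 of 8 animals; without dosed replicate 2 Serpina9 had log2FC -5.17. The uncharacterised 2010003K11Rik rose 4.42-fold (log2FC 2.15, SE 0.50, adjusted p = 0.00397, 7 of 8 animals). The mitotic genes Cdc20 (log2FC 3.41, SE 0.89, adjusted p = 0.0119), Ccna2 (3.27, SE 0.75, adjusted p = 0.0038) and Kif20a (2.90, SE 0.67, adjusted p = 0.00401) rose, and each was lost without replicate 7 (log2FC 2.07, 2.23 and 1.71, adjusted p = 0.191, 0.0658 and 0.116). The hepatokine Lect2 (log2FC -0.94, SE 0.25, adjusted p = 0.014) and the ascorbate enzyme Gulo (-0.80, SE 0.23, adjusted p = 0.022) were among the pericentral genes that fell, and Gulo was lost without replicate 8 or 9. Serpina9 was lost in limma, Dnaic1 with the groups fitted alone, Lect2 and Gulo with the covariate, Lect2 also without replicates 1 and 7, and Cdc20, Ccna2 and Kif20a in each of these 4 settings, while 2010003K11Rik passed in every alternative run. Probes of 1 gene did not always match in call: a further probe did not pass for Abcb11, Abcc4, Acot3, Aldh2, Bst2, Ccna2, Cdk1, Crat, Cyp2c54, Ecm1, Hsp90b1, Rrm2, Serpina1a, Slc1a2, Ebp, Lss, Cyp17a1, Reln or Mup19 (Mup19_68456, log2FC -0.08). A further probe did pass for Apob, the main protein of low-density lipoprotein (Apob_68264, log2FC -0.75, adjusted p = 0.00234), and for Creb3l3, a regulator of lipid genes.

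Over all genes at 40 mg/mL for 14 d, edgeR called 1111 features, of which 320 changed more than 2-fold, and the median size of a called log2 fold change was 0.77. The count was 696 in limma and 645 with the groups fitted alone, 464 with the failed library kept, 555 with the log2 scaling factor as a covariate (172 shared) and 273 without replicates 1 and 7. Leaving out 1 library gave 584 (replicate 1 or 7) to 1496 (replicate 6). Among the named genes 93 were called in the full fit, of which 45 stayed called in every leave-one-out run, and 48 were lost in at least 1.

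**Figure D1:**
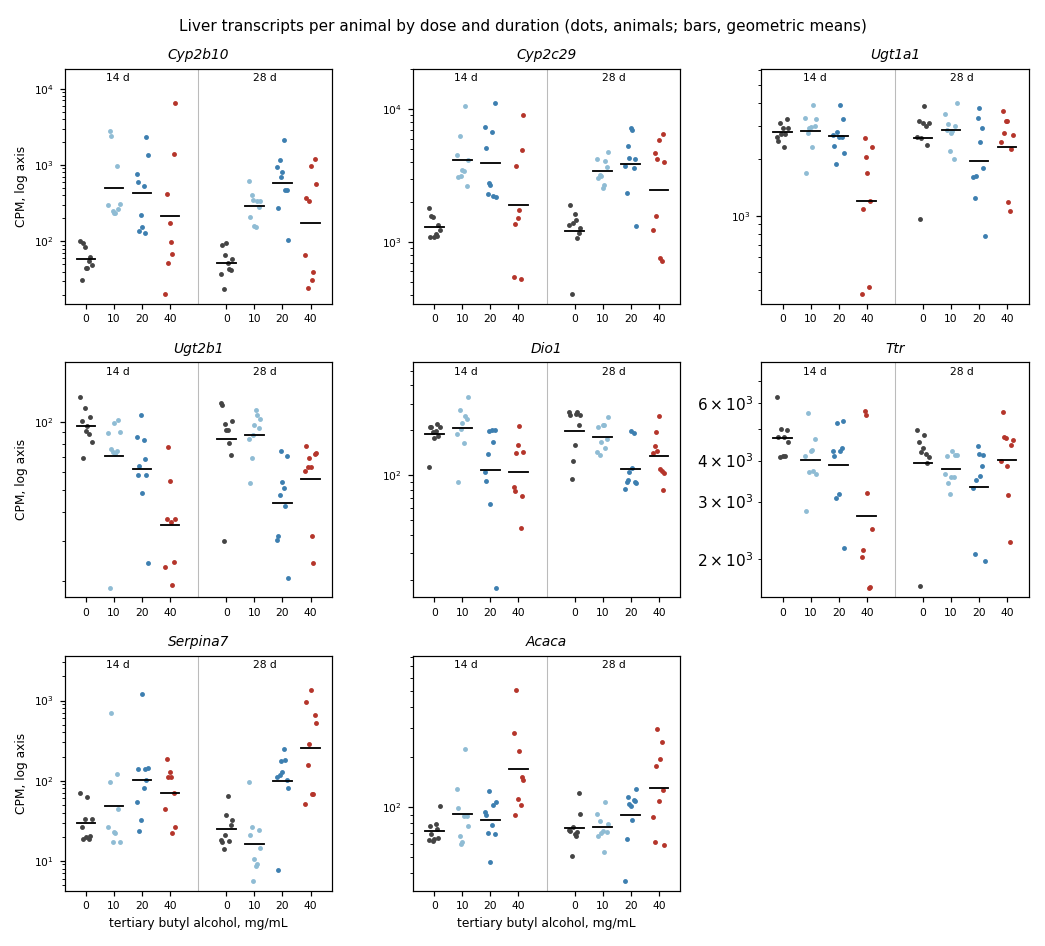
Expression of 8 genes in CPM on a log axis, by dose in mg/mL and duration, with each animal as a dot and the geometric mean of each group as a bar. Cyp2b10 was higher in all animals at 10 and 20 mg/mL and spread widely at 40 mg/mL.

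**Figure D2:**
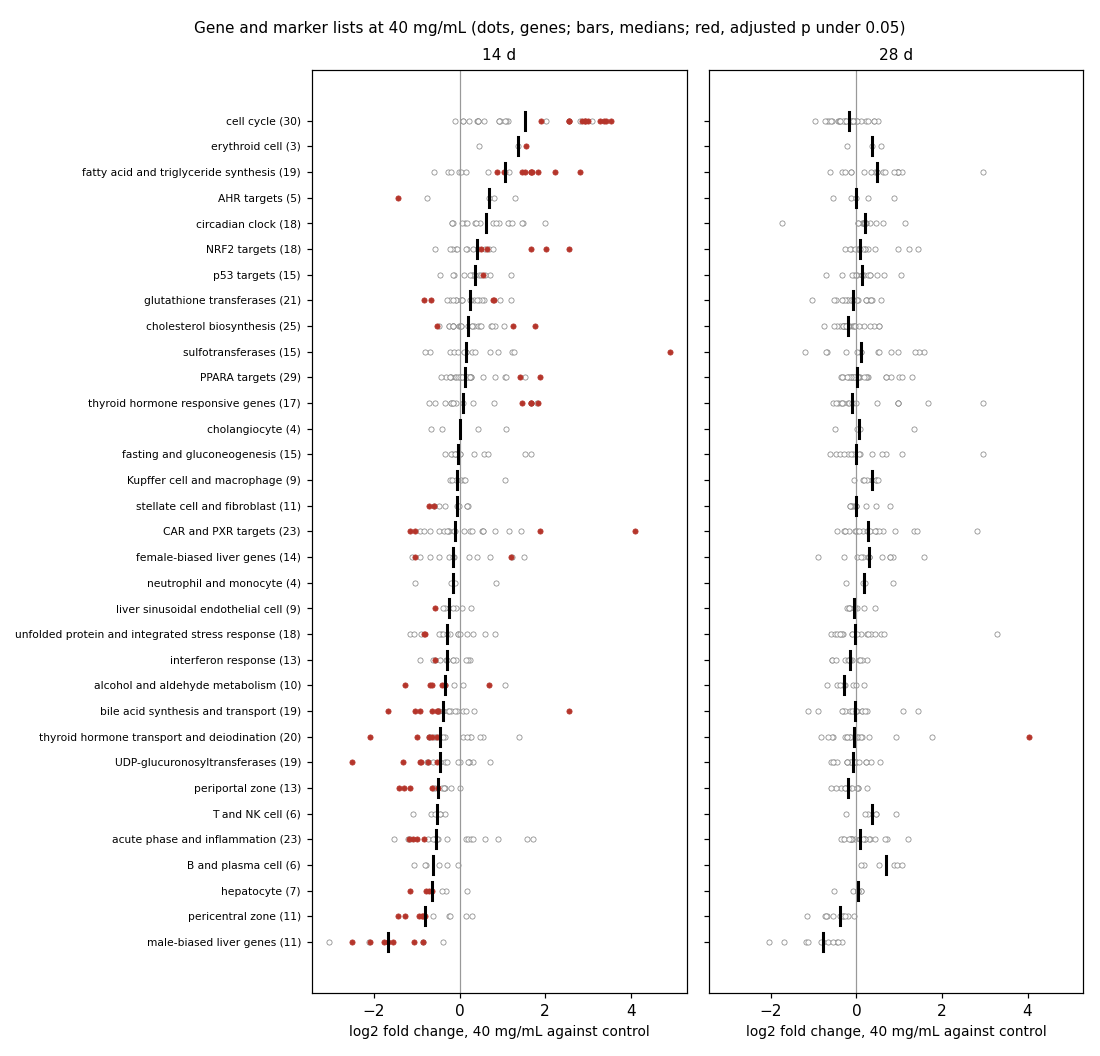
Log2 fold change at 40 mg/mL against control for the genes of each list at 14 d (left) and 28 d (right), with genes as dots (red where adjusted p was under 0.05) and list medians as black bars. The male-biased list lies lowest at both durations.

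At 10 mg/mL for 14 d no feature passed in edgeR (0 of 17050, 736 at unadjusted p under 0.05, smallest adjusted p = 0.0759), yet the CAR and PXR targets were higher as a list. Of 23 measured, 21 had positive values, and 7 rose and 0 fell adjusted over the list alone (median 0.47, n = 9 and 9; camera adjusted p = 5.7e-08 with the preset correlation and 0.10 with an estimated correlation). Cyp2b10 averaged 855 ± 1003 CPM (SD) against 63.2 ± 25, above all controls in 9 of 9 animals (log2FC 3.76, SE 0.79, adjusted p = 0.0878), and Cyp2c29, a steroid and drug hydroxylase, also had 9 of 9 above (log2FC 1.79, adjusted p = 0.0978). In exact permutation tests of 19 genes over 6 comparisons, Cyp2b10 (log2 CPM difference 3.09), Cyp2c29 (1.67), Por (0.80) and the fatty acid hydroxylase Cyp4a14 (1.73) were higher. Of the PPARA targets 7 rose adjusted over the list alone (median 0.19, camera adjusted p = 1.4e-06 with the preset correlation and 0.17 with an estimated correlation). All 13 interferon response genes had negative values (median -0.55, camera adjusted p = 1.6e-13 with the preset correlation and 0.079 with an estimated correlation), and Kupffer markers had a median of -0.36 (1.4e-05, and adjusted p = 0.091 with an estimated correlation). Other markers were lower too: all 6 T and NK (median -0.46), all 4 neutrophil (-0.52) and all 3 erythroid markers (-0.80) had negative values, as did 9 of 11 stellate markers (-0.23). Their camera adjusted p was 0.0085, 0.0046, 0.0039 and 0.0012 with the preset correlation and 0.091, 0.091, 0.13 and 0.091 with an estimated correlation. Counts were 12 in DESeq2, 7 in limma and in the groups alone, 6 without robust fitting, 3 at 5 CPM, 2 with surrogate variables, 8 with the covariate and 4 without replicates 1 and 7 of the top dose. Leaving out 1 library gave 0 to 5: 5 without dosed replicate 8, 3 without control 2 and 1 without control 3 or dosed 2 or 6.

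At 20 mg/mL for 14 d, 6 features passed, 5 higher and 1 lower (1032 at unadjusted p under 0.05, n = 9 and 9). Cyp2a22 and Cyp2c55, cytochrome P450 enzymes, rose 4.39-fold (log2FC 2.13, SE 0.35, adjusted p = 0.00106) and 8.67-fold (log2FC 3.12, SE 0.63, adjusted p = 0.0289). The aldo-keto reductase Akr1b10 rose 1.89-fold (log2FC 0.92, SE 0.19), the chemokine Cxcl1 6.48-fold (log2FC 2.69, SE 0.58, adjusted p = 0.0499) and the acute phase protein Saa2 66.4-fold (log2FC 6.05, SE 1.30, adjusted p = 0.0499), while Serpina1e was 4.94-fold lower by probe Serpina1e_62853 (log2FC -2.31, SE 0.45, adjusted p = 0.0257) but did not pass by its other probe (log2FC -0.48, adjusted p = 0.7). Cyp2b10 was above all controls in 9 of 9 animals but did not pass (690 ± 734 CPM, log2FC 3.45, SE 0.78, adjusted p = 0.0508), nor did Cyp2c29 (log2FC 1.83, adjusted p = 0.0508). Among the 23 CAR and PXR targets 1 rose, Cyp2c55 (5 adjusted over the list alone; median 0.46, camera adjusted p = 3.3e-06 with the preset correlation and 0.36 with an estimated correlation). Male-biased genes had a median of -0.85, with 7 fallen adjusted over the list alone (camera adjusted p = 1.1e-10 with the preset correlation and 0.0058 with an estimated correlation). By exact permutation Cyp2b10 (log2 CPM difference 2.84), Cyp2c29, Sult1a1 (0.53), Sult2a1 (2.91) and Cyp4a14 (1.31) were higher and Ugt2b1 was lower (-0.63). Counts were 13 at 5 CPM or without robust fitting, 21 in DESeq2, 18 in limma, 20 with surrogate variables, 25 with the covariate, 11 with probes summed and 1 with the failed library kept. Of the 6 calls, 6 were kept at 5 CPM, 5 in DESeq2, 4 in limma and only 1 with the 2 groups fitted alone, which gave 9. Leaving out 1 library gave 1 (control 4) to 14 (dosed 4), with 12 without dosed 3 or 7, 10 without control 3, 3 without control 2 or 5, and 2 without control 6, 7, 8 or 9 or dosed 5.

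Across the 14 d doses 1362 features had a linear trend (622 up, 740 down; 1122 symbols). Mup20 fell by 0.455 log2 units per 10 mg/mL (adjusted p = 9.67e-05) and Cyp7b1 by 0.397 (adjusted p = 0.000941). Acaca rose by 0.345 (adjusted p = 0.000278), Pnpla3 by 0.643 (adjusted p = 0.00707) and Mki67 by 0.869 (adjusted p = 0.00684). Dio1, which had missed in the top-dose comparison, fell by 0.215 per 10 mg/mL (adjusted p = 0.0361). The trend count was 782 in limma, 430 with the covariate, 658 with the failed library kept and 232 without replicates 1 and 7. Without replicate 7 or 1 alone it was 699 or 714, and without replicate 6 it was 1833.

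At 10 mg/mL for 28 d no feature passed in edgeR (0 of 17050, 707 at unadjusted p under 0.05, smallest adjusted p = 0.999, n = 9 and 9). CAR and PXR targets again had higher values as a list (median 0.40, 4 risen and 0 fallen adjusted over the list alone; camera adjusted p = 4.1e-13 with the preset correlation and 0.053 with an estimated correlation). Cyp2b10 stood at 315 ± 141 against 56.5 ± 24 CPM (SD), above all controls in 9 of 9 animals (log2FC 2.48, adjusted p = 0.999), and Cyp2c29 at 3478 ± 761 against 1296 ± 417 CPM in 9 of 9 (log2FC 1.42). By exact permutation Cyp2b10 (2.47), Cyp2c29 (1.49), Por (0.54) and Sult1a1 (0.37) were higher. All 14 female-biased liver genes had positive values (median 0.57, camera adjusted p = 5.8e-10 with the preset correlation and 0.048 with an estimated correlation). The sulfotransferase list had a median of 0.50 (camera adjusted p = 0.0002 with the preset correlation and 0.098 with an estimated correlation). DESeq2 gave 0 calls, limma 18 and the groups alone 11.

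At 20 mg/mL for 28 d, 27 features of 26 symbols passed, 11 higher and 16 lower, all with adjusted p of 0.0497 to 0.0499 (2583 at unadjusted p under 0.05, n = 9 and 9). Cyp2b10 rose 13.8-fold (log2FC 3.78, SE 0.79, adjusted p = 0.0497), to 778 ± 593 CPM (SD), with 9 of 9 animals above all controls. Cyp2c29 rose 3.34-fold (log2FC 1.74, SE 0.40), Cyp2a22 2.91-fold (log2FC 1.54, SE 0.34) and the glutathione transferase Gstm1 1.83-fold (log2FC 0.87, SE 0.20). Of the genes lower at 40 mg/mL for 14 d, Mup20 was 2.61-fold lower (log2FC -1.38, SE 0.30), Slc22a28 3.45-fold (log2FC -1.79, SE 0.41) and Gm10681 9.63-fold (log2FC -3.27, SE 0.71). Serpina1e was 3.89-fold lower by probe Serpina1e_62853 (log2FC -1.96, SE 0.44) and did not pass by its other probe (log2FC -0.50, adjusted p = 0.22). Slco1a1 was 5.27-fold lower (log2FC -2.40, SE 0.57) and Acsm2, which activates medium-chain acids, 3.61-fold lower (log2FC -1.85, SE 0.44). Of 11 male-biased genes 2 fell (7 adjusted over the list alone; median -1.19, camera adjusted p = 4.6e-08 with the preset correlation and 0.031 with an estimated correlation). Pericentral genes had 0 calls but 8 fallen adjusted over the list alone (median -0.80, camera adjusted p = 1.2e-06 with the preset correlation and 0.035 with an estimated correlation). For CAR and PXR targets 2 rose and 0 fell (4 rose adjusted over the list alone; median 0.15, camera adjusted p = 0.0032 with the preset correlation and 0.85 with an estimated correlation). Ugt2b1 had log2FC -0.92 (adjusted p = 0.0759) and Dio1 -0.85 (adjusted p = 0.122), and by exact permutation both were lower (-0.93 and -0.85).

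The 20 mg/mL calls at 28 d, Cyp2b10 and Mup20 among them, sat at the edge of the threshold and rested on many libraries. The count was 299 in DESeq2, 515 in limma, 101 at 5 CPM, 52 with the groups alone, 63 with probes summed, 70 without replicates 1 and 7 at 40 mg/mL for 14 d, 12 with the covariate and 9 with surrogate variables. It was 0 with another scaling method, with no expression filter or with the failed library kept. Without control replicate 3 it was 760, without dosed 7 it was 348, without dosed 9 it was 8 and without dosed 5 it was 1. It was 0 without any of controls 1, 2 and 4 to 9 or dosed 1, 2, 3, 6 and 8.

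At 40 mg/mL for 28 d only Serpina7, the gene of thyroxine-binding globulin, passed (1 of 17050 features, 1078 at unadjusted p under 0.05). Serpina7 rose 16.5-fold (log2FC 4.04, SE 0.75, adjusted p = 0.0166, n = 9 and 9), from 27.8 ± 15.7 to 457 ± 456 CPM (SD), and 8 of 9 animals were above all controls. Its second probe Serpina7_78674 had log2FC 4.10 (adjusted p = 0.0576). At 20 mg/mL for 28 d Serpina7 stood at 128 ± 68 CPM with 8 of 9 animals above all controls (log2FC 2.21, SE 0.69, adjusted p = 0.122), and at 40 mg/mL for 14 d it had log2FC 1.38 (SE 0.69, adjusted p = 0.259). Serpina7 was lost without any of 28 d controls 1, 2, 4, 7 and 8 (highest adjusted p = 0.0656). The count was 40 in DESeq2, 218 in limma, 25 with the groups alone, 8 at 5 CPM, 6 without robust fitting, 42 with surrogate variables, 66 with the covariate and 5 with probes summed. It was 17 without dosed 5, 8 without control 3, 3 without dosed 6 or 7 and 2 without dosed 1 or 2.

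Below that threshold several genes of the 14 d response kept their sign at 40 mg/mL for 28 d. Elovl3 had log2FC -2.04 (SE 0.44, adjusted p = 0.0641) with 9 of 9 animals below all controls, and it passed in DESeq2 and limma. Oat, the aminotransferase of ornithine, had log2FC -1.16 (SE 0.26, adjusted p = 0.0736) with 8 of 9 below, and passed in DESeq2 and limma. Pnpla3 had log2FC 2.95 (SE 0.70, adjusted p = 0.107) and Acaca 0.98 (SE 0.26, adjusted p = 0.221). The hepatic hormone Fgf21, not called at 14 d (log2FC 1.68, adjusted p = 0.207), had 2.95 at 28 d (SE 0.76, adjusted p = 0.163). Cyp2b10 had log2FC 2.83 (SE 0.76, adjusted p = 0.221) with 5 of 9 animals above all controls. In DESeq2 Pnpla3, Fgf21, Acaca and Cyp2b10 passed as well. Male-biased genes had 0 calls, 5 fallen adjusted over the list alone and a median of -0.78 (camera adjusted p = 8e-12 with the preset correlation and 0.0029 with an estimated correlation). Pericentral genes had a median of -0.39 and 3 fallen adjusted over the list alone (camera adjusted p = 3.3e-08 with the preset correlation and 0.011 with an estimated correlation). Fatty acid synthesis had a median of 0.47 and 7 risen adjusted over the list alone (camera adjusted p = 0.00035 with the preset correlation and 0.57 with an estimated correlation). Ugt1a1 (log2FC -0.15, adjusted p = 0.981), Ugt2b1 (-0.59, 0.694) and Ttr (0.02), which had fallen at 14 d, did not pass. Dio1, at its most abundant probe, passed at neither duration (-0.56, adjusted p = 0.776 at 28 d). The UDP-glucuronosyltransferase list had 0 calls (median -0.07, camera adjusted p = 0.24), and the cell cycle list had 0 calls (median -0.18, camera adjusted p = 0.27).

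Across the 28 d doses 22 features of 18 symbols passed the same linear contrast (13 up, 9 down). Serpina7 rose by 1.12 log2 units per 10 mg/mL (SE 0.17, adjusted p = 0.000197), and both of its probes passed. Fgf21 rose by 0.90 (adjusted p = 0.014; 0.99 and 0.00933 by its other probe Fgf21_71031), Pnpla3 by 0.77 (SE 0.16, adjusted p = 0.0166), the leptin receptor Lepr by 0.54 and Cyp2a22 by 0.37. Elovl3 fell by 0.51 (SE 0.11, adjusted p = 0.0206), Oat by 0.31 (adjusted p = 0.0157) and the sulfotransferase Sult1b1 by 0.19 (adjusted p = 0.0428). The count was 66 with the 28 d groups alone, 74 in DESeq2, 350 in limma, 132 with surrogate variables, 170 with the covariate and 4 with the failed library kept. Without 1 of the 40 mg/mL replicates it was 6 (replicate 3), 7 (4), 8 (7), 14 (6) and 42 (5), and it was 11 without control 1 and 13 without control 7.

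Whether the dose effect differs between durations depended on the test. The interaction test called 0 features at 10, 20 and 40 mg/mL in edgeR (732, 537 and 1081 at unadjusted p under 0.05; smallest adjusted p at 40 mg/mL = 0.222). In DESeq2 the interaction at 40 mg/mL gave 25 calls, surrogate variables gave 14 and limma gave 2 at 10 mg/mL. Serpina7 differed by 2.66 log2 units at 40 mg/mL (adjusted p = 0.52), Acaca by -0.48 (0.944) and Mki67 by -3.66 (0.522). Ugt1a1 differed by 0.784 (adjusted p = 0.705) and Ttr by 0.662 (0.646). Controls at 28 d and 14 d did not differ in edgeR (0 calls, 516 at unadjusted p under 0.05, smallest adjusted p = 0.433), with 3 in limma and 1 with the covariate or with probes summed. Leaving out 28 d control replicate 3 gave 1.

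**Figure D3:**
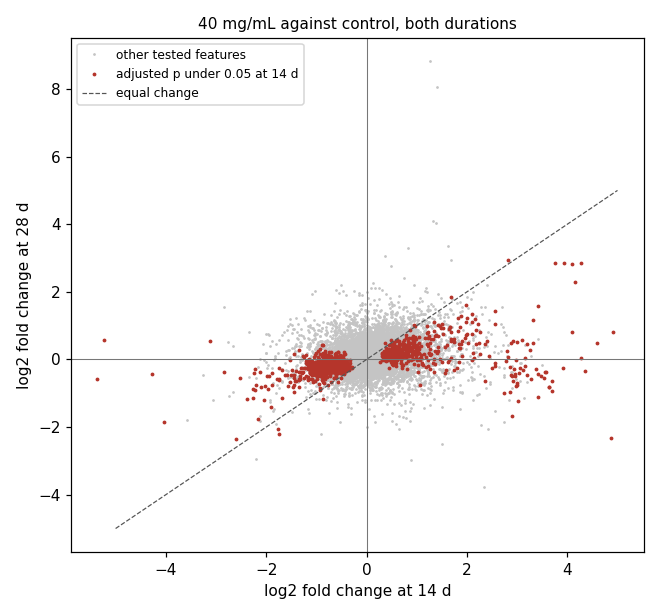
Log2 fold change at 40 mg/mL against control at 14 d (horizontal) and 28 d (vertical), with each tested feature as a dot, features with adjusted p under 0.05 at 14 d in red and equal change as a dashed line. Most red features keep their sign at 28 d; they were picked on their 14 d values, so smaller values at 28 d would follow even from equal effects.

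Cyp2a22 and the probe Serpina1e_62853 passed at 20 mg/mL at both durations, and no feature passed at 40 mg/mL at both in edgeR (23 did in DESeq2). At 14 d the 20 and 40 mg/mL groups shared 3 features, 2 higher and 1 lower, where 0.179 would be shared by independence, and the 2 comparisons use the same controls. At 14 d the correlations of 10 with 20, 10 with 40 and 20 with 40 mg/mL were 0.437, 0.420 and 0.523 across genes, not independent replicates. Simulated groups without change that share a control gave means of 0.352, 0.335 and 0.335 (highest 0.511, 0.489 and 0.492). With the controls divided between the doses the 14 d correlations lay between 0.0609 and 0.240. At 28 d the same pairs had 0.505, 0.440 and 0.490 across genes, with simulated means of 0.296, 0.295 and 0.298 (highest 0.434, 0.430 and 0.437) and -0.0262 to 0.230 with divided controls. Of the 1111 features called at 40 mg/mL for 14 d, 724 (65.2%), 1001 (90.1%) and 941 (84.7%) had the same sign at 10, 20 and 40 mg/mL at 28 d, where the controls are other animals. Mean TMM factors in these 28 d groups were 0.960, 1.14 and 1.05, against 0.927 in 28 d controls, so the agreement was highest where the factors were. A shared difference in library composition and a dose effect cannot be told apart by this agreement. Over all tested features the correlation between durations was 0.0273, 0.247 and 0.232 at 10, 20 and 40 mg/mL (across genes, not independent replicates).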

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

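The tests of other cell types, of rescaling, of the 2 libraries with the highest factors, of lymphoid markers, of 28 d control replicate 3 and of thinned counts were chosen only after results had been seen, while those of erythroid markers, equal effects and depth were set before. The covariate was itself chosen after the data had been seen, and only the limits for its slope were set before that slope was known.

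Of 72 groups of values (8 genes and the library totals), 15 held an animal standing well apart, 10 as the highest and 5 as the lowest. In normally distributed values chance flags about 1 in 20 groups. The values here were not logged, so the share that chance would flag is not known. The library of replicate 5 at 40 mg/mL for 14 d had 0.0108 M counts where the next had 8.32 M. Cyp2b10 reached 6424 CPM in replicate 9 at 40 mg/mL for 14 d (next 1380), and Cyp2c29 10505 CPM in replicate 7 at 10 mg/mL for 14 d (next 6247). The 28 d control replicate 3, whose scaling factor was high, was lowest for Ugt1a1 (965 CPM, next 2386) and Ttr (1662, next 3944). The 14 d control replicate 1 was lowest for Dio1 (114, next 177) and highest for Ttr (6261, next 4977). Ugt2b1 was at 18.7 CPM in replicate 2 at 10 mg/mL for 14 d (next 72.1). Serpina7 stood apart in 4 groups: 707 CPM in replicate 3 at 10 mg/mL (next 120) and 1211 in replicate 5 at 20 mg/mL for 14 d (next 142), 64.2 in 28 d control replicate 6 (next 37.0) and 95.2 in replicate 1 at 10 mg/mL for 28 d (next 26.2). Acaca was highest in 14 d control replicate 9 (101, next 78.7), in replicate 7 at 10 mg/mL (223, next 128) and in replicate 3 at 40 mg/mL for 14 d (503, next 278).

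The lower hepatocyte markers at 40 mg/mL for 14 d may have several sources. Mean log2 CPM of the hepatocyte markers was -0.69 against control (exact permutation p = 0.000452, 95% interval -1.06 to -0.33, 6 of 8 animals below all controls). A lower share of hepatocytes in the sections would raise the markers of other cells. At the scaling used, 49 markers of 7 other cell types were not higher but averaged -0.31 (exact permutation p = 0.0271, interval -0.60 to -0.04). The 3 erythroid markers, outside that average, averaged 0.58 (exact permutation p = 0.321). The test cannot decide on a lower share. It takes the scaling factors as right (mean 1.24 against 0.897 in controls), and the other markers fell less than the hepatocyte markers. Scaling factors that misplace all features and a real fall cannot be told apart by rescaling, because the 2 other scalings, with 4 of 4 markers still called, moved the fold changes by a median of only 0.00957 and -0.0182 log2 units. A composition axis that an undosed library also shows could hold part of the change: with the log2 scaling factor as a covariate the slope of the log2 fold changes on those without it was 0.62 (0.546 to 0.699 leaving out 1 library), 1014 of 1111 features (91.3%) had the same sign, 172 were still called and the hepatocyte median was -0.13. An effect of the dose on composition and a composition effect unrelated to dose cannot be told apart, since the slope lies between the limits set for either and dose and factor rise together at 14 d.

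Higher cell cycle transcripts at 40 mg/mL for 14 d could come from few animals. The mean of the list was 0.76 log2 units above control (exact permutation p = 0.184), with 4 of 8 animals above all controls and 2 below. Without replicates 1 and 7 the median was 0.88 in place of 1.52, 0 members were called in edgeR and 25 of 30 were positive, so these 2 libraries alone and a wider rise cannot be told apart. For dividing lymphoid cells, 12 T, NK, B and plasma cell markers averaged -0.65 (exact permutation p = 0.0151, interval -1.14 to -0.16). At the scaling used, 0 of 8 animals were above all controls for them and 5 were below. The test cannot exclude such cells, since these markers lay near the floor (mean log2 CPM -0.26 against 0.39) and depend on the scaling factors. Erythroid precursors remain open: their markers (mean difference 0.58, exact permutation p = 0.321) followed the cell cycle genes over the 8 dosed animals with r = 0.657 (exact permutation p = 0.084, interval -0.09 to 0.93) and with a rank correlation of 0.762 (exact permutation p = 0.0368), while r fell to 0.326 without the 2 farthest animals.

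More features passed at 40 mg/mL for 14 d (1111) than for 28 d (1), and the difference may not be one of biology, since 0 interactions were called in edgeR (1081 at unadjusted p under 0.05, 25 in DESeq2). The 28 d control with the high factor does not account for it, since 8 features were called without it. Depth is argued against too: the 28 d libraries held 0.911 of the 14 d totals (interval 0.85 to 0.982), but thinning the 14 d counts to that depth gave 1114 calls. For 200 features picked in part of the animals, the slope at 28 d over that in held-out 14 d animals had a median of 0.467 (0.345 to 0.638 over 20 draws). The median is below what equal effects were set to give (over 0.8). Equal effects under a larger spread and a weaker effect at 28 d cannot be told apart, because the limit set for excluding equal effects was a ratio under 0.6 in every draw and the highest draw was 0.638.

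Splits of the same animals into groups of the same sizes show how often other groupings gave as many calls. With 100 splits the real one is at least 1 of 100, and the shares were not adjusted over the comparisons. For 40 mg/mL at 14 d, 1 of the 100 splits, the real one, gave as many as 1111 features, but the highest other gave 910 and 20 others gave at least 1. At 20 mg/mL 1 of the 100 splits gave as many at 14 d (6, highest other 1) and at 28 d (27, highest other 3), as it did for 40 mg/mL at 28 d (1, highest other 0) and for the 14 d trend (1362, highest other 122). No other drawn split reached these counts, but those of 27 and 1 at 28 d fell to 0 in 13 and 5 of 18 leave-one-out runs. For the 28 d trend 2 of the 100 splits gave as many (22, highest other 574), which points to a structure of the samples. At 10 mg/mL the real count was 0 at 14 d (highest other 2) and at 28 d (highest other 0), as it was for the interactions at 10, 20 and 40 mg/mL (highest other 0, 1 and 93) and the control comparison (0). All 100 splits reach a count of 0 whatever the data, so the splits say nothing about chance there. These 0 counts are from edgeR; unadjusted p under 0.05 was reached by 736 and 707 features at 10 mg/mL, by 732, 537 and 1081 for the interactions and by 516 between controls, and DESeq2 gave 12 at 10 mg/mL for 14 d.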

How the results depend on the processing

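The failed library kept, the 2 libraries of highest factor left out, the covariate, the exact tests of named genes and the totals without the failed library were chosen after seeing the data. A depth limit set relative to the median library removed none beyond the failed one. The cause was not tested for any difference below. Counts are of features called, with the edgeR value first.

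Tests. At 10 mg/mL for 14 d (0; 736 at unadjusted p under 0.05) DESeq2 gave 12, limma 7 and edgeR without robust fitting 6; at 20 mg/mL (6) they gave 21, 18 and 13. At 40 mg/mL for 14 d (1111) limma gave 696, and for the 14 d trend (1362) 782. At 10 mg/mL for 28 d (0; 707 at unadjusted p under 0.05) limma gave 18. At 20 mg/mL for 28 d (27) DESeq2 gave 299 and limma 515. At 40 mg/mL for 28 d (1) DESeq2 gave 40, limma 218 and non-robust fitting 6, and for the 28 d trend (22) DESeq2 gave 74 and limma 350. Interactions (0; 732 and 1081 at unadjusted p under 0.05) became 2 in limma at 10 mg/mL and 25 in DESeq2 at 40 mg/mL, and the control comparison (0; 516 at unadjusted p under 0.05) 3 in limma. In DESeq2 the doses shared 6 features (10 and 20 mg/mL), 6 (10 and 40) and 12 (20 and 40) at 14 d and 13 (20 and 40) at 28 d, and the durations 9 at 20 mg/mL and 23 at 40 mg/mL. At an adjusted p under 0.01, 20 and 40 mg/mL shared 1 at 14 d and the durations 0 at 20 mg/mL.

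Scaling and filters. At 20 mg/mL for 28 d (27) RLE scaling gave 0, scaling without the top 20 features 0, no filter 0 (2583 at unadjusted p under 0.05 in edgeR, 299 in DESeq2), a 5 CPM filter 101 and summed probes 63. The 5 CPM filter gave 3 at 10 mg/mL and 13 at 20 mg/mL for 14 d and 8 at 40 mg/mL for 28 d. Summed probes gave 11 at 20 mg/mL for 14 d, 5 at 40 mg/mL for 28 d and 1 between controls.

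Samples and covariates. With the groups of a comparison alone, 10 mg/mL for 14 d gave 7, 40 mg/mL for 14 d 645, 10, 20 and 40 mg/mL for 28 d 11, 52 and 25, and the 28 d trend 66. Surrogate variables gave 2 and 20 at 10 and 20 mg/mL for 14 d, 9 and 42 at 20 and 40 mg/mL for 28 d, 132 for the 28 d trend and 14 for the interaction at 40 mg/mL. With the covariate the 14 d counts were 8 (10 mg/mL), 25 (20) and 555 (40; 172 of the 555 shared), with 12 and 66 at 20 and 40 mg/mL for 28 d, 430 and 170 for the trends at 14 and 28 d and 1 between controls. The failed library kept gave 1 and 464 at 20 and 40 mg/mL for 14 d, 0 at 20 mg/mL for 28 d, 658 for the 14 d and 4 for the 28 d trend. Without replicates 1 and 7 there were 4 at 10 mg/mL and 273 at 40 mg/mL for 14 d, 70 at 20 mg/mL for 28 d and 232 for the 14 d trend.

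Direction of genes at 40 mg/mL for 14 d. With the covariate Cyp3a11 was 0.62, Ugt1a6a 0.013, Ugt1a9 1.63, Ugt2b34 0.24, Dio1 0.04, Cyp2c54 0.0639 and Aldh2 0.0017. Ugt1a9 was 0.34 with surrogate variables and 0.0706 without replicates 1 and 7, Ugt2b35 -0.15 with probes summed and Ccnb1 -0.50 in limma. At 28 d Cyp3a11 was 0.16 with surrogate variables and 0.44 with the covariate, Ugt1a1 0.0046 and 0.26, and Ugt1a6a 0.11 in limma, 0.11 with the covariate and 0.095 with probes summed. Ugt2b34 was 0.0032 with RLE scaling, 0.0155 at 5 CPM, 5e-04 with the groups alone, 0.0032 in DESeq2, 0.096 with surrogate variables, 0.29 with the covariate and 0.0026 with probes summed. Sult1a1 was -0.012 in the exact tests, Ttr -0.0058 in limma and Mki67 0.019 with probes summed. The naming rule gives 207 features in each 40 mg/mL comparison, 93 and 1 of them called at 14 and 28 d. In some alternative 42 and 35 of the 207 turned direction, 3 (Cyp2c54, Aldh2 and Ccnb1) and 0 of them called, with 65 turned values at each duration, the largest 1.63 and 0.47 in size. Of these values 54 and 48 belong to features whose values the text does not give. The genes whose values are printed were chosen after the values had been seen.

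Leaving out 1 library gave 0 to 5 at 10 mg/mL, 1 to 14 at 20 mg/mL and 584 (replicate 1 or 7) to 1496 (replicate 6) at 40 mg/mL for 14 d, 0 to 760 at 20 mg/mL and 0 to 17 at 40 mg/mL for 28 d. The 14 d trend gave 699 to 1833, the 28 d trend 6 to 42 and the control comparison 0 to 1. The report names the libraries. Directions turned in Sult1d1 at 40 mg/mL for 14 d (-0.20 to 1.05) and, for 28 d, in Cyp3a11 (-0.17 to 0.0802), Ugt1a6a (-0.20 to 0.13), Ugt2b34 (-0.11 to 0.0928), Sult1a1 (-0.0813 to 0.16), Sult1d1 (-0.092 to 0.21), Ttr (-0.082 to 0.11) and Mki67 (-0.75 to 0.28).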

Other observations

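Further gene groups at 40 mg/mL for 14 d gave few calls. Of 14 female-biased liver genes 1 rose, the steroid hydroxylase Cyp17a1 (log2FC 1.21, SE 0.36, adjusted p = 0.0264, n = 8 against 9), and 1 fell; the median was -0.15, the mean 0.03 and the camera direction down (adjusted p = 0.95). Fasting and gluconeogenesis genes had 0 calls in edgeR, a median of -0.03, a mean of 0.25 and a camera direction up (adjusted p = 0.9), and circadian clock genes 0 calls and a median of 0.62 (camera adjusted p = 0.016 with the preset correlation and 0.15 with an estimated correlation). Among cholesterol genes Mvd (log2FC 1.75, SE 0.50) and Lss (1.24, SE 0.39) rose and Ebp (-0.54, SE 0.15) fell (median 0.20, camera adjusted p = 0.8), glutathione transferases had a median of 0.24 (0.61), and p53 targets 0.35 (0.025, and adjusted p = 0.15 with an estimated correlation). The unfolded protein response had a median of -0.30 (0.014, and adjusted p = 0.32 with an estimated correlation) and the interferon genes -0.31 (0.0027, and adjusted p = 0.36 with an estimated correlation). Cyp17a1 was lost without control 4 or 5 or dosed 9 (highest adjusted p = 0.347), and its lowest log2FC without 1 library was 0.593. Mvd was lost without dosed 1 or 9 (0.0846) and Ebp without control 1 or dosed 1 or 8 (0.0654). Lss was lost without control 1, 3, 4, 5, 7 or 9 or dosed 1, 8 or 9 (0.286), and its lowest log2FC without 1 library was 0.745.

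Marker medians at 40 mg/mL for 14 d were -0.06 for Kupffer cells (mean 0.08, camera direction down, adjusted p = 0.5), -0.24 for sinusoidal endothelium (0.021, and adjusted p = 0.36 with an estimated correlation), -0.07 for stellate cells (0.087), 0.01 for cholangiocytes (0.96), -0.52 for T and NK cells (0.032, and adjusted p = 0.16 with an estimated correlation), -0.63 for B cells (0.14), -0.15 for neutrophils (0.27), 1.36 for erythroid cells (0.27) and -0.25 for 2 markers of exocrine pancreas, too few to test. The endothelial gene that fell was Oit3 (log2FC -0.58, SE 0.18, adjusted p = 0.0363), lost without control 3, 4, 7, 8 or 9 or dosed 1, 2, 7, 8 or 9 (highest 0.115), and the stellate genes were Ecm1 (-0.59, SE 0.14, adjusted p = 0.00401) and Reln (-0.71, SE 0.21, adjusted p = 0.0263), a matrix protein and a secreted signal; Reln was lost without control 6 or 9 or dosed 1, 4, 8 or 9 (0.0767).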
